A study of Mus musculus with 8 samples.

How the data were processed

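Total RNA from mouse prostate was hybridised to Affymetrix arrays, with RNA accepted at an integrity score of 2.0 or more per the labels. The integrity of each sample is not given in the sources used here. The deposited table held log2 values, 1 row per probe set and 1 column per array, for 20670 probe sets and 8 arrays. The log base is not stated and was taken as 2 because values ran from 5.14 to 14.45. The authors' normalization and summarisation are not given in the sources used here. The array quartiles differ, so the values were not quantile-identical after summarisation. The submitters' processing notes name the mouse genome build mm9. The gene annotation at hand was of another build, so no coordinates are printed. Of the probe sets, 1546 (7.48%) had an SD under 0.01 over the 8 arrays. Among the genes tested, 1317 had such an SD, and none of these was called in any comparison.

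Probe sets with exactly 1 gene symbol numbered 18591, of which 18564 matched a RefSeq gene by Entrez number. A further 489 carried several symbols and 1590 none, and both sorts were left out. Where a gene had several probe sets, the one with the highest mean over the 8 arrays was used, which left 18460 genes. Pten, Trp53, Cdkn1a, Ar, Nkx3-1 and Gapdh had no probe set of their own by this rule and were not analysed here.

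Groups came from the sample titles, and array batches from the prefix of the array names in the sample descriptions. Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Genotype was fitted on all 8 arrays with age and batch as covariates (4 residual degrees of freedom), so the contrast rests on batch 1, which holds 2 double mutant and 2 wild type arrays, while batch 2 adds to the estimate of spread. Age was fitted on the 6 wild type arrays with batch as a covariate (3 residual degrees of freedom), the interaction on all 8 arrays with batch (3), and batch on the wild type arrays with age. The exact permutation of 2 against 6 arrays, which ignores batch and age, cannot go below a two-sided p of 0.0714. Within batch 1, on which the fitted contrast rests, there are fewer arrays and the bound is higher. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

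Gene lists numbered 36, with 577 genes, of which 506 were measured. The 34 lists with at least 5 measured members were tested with limma's camera, at a preset inter-gene correlation of 0.01, adjusted over the lists. The calls were repeated with the correlation estimated from the data and with fry, whose directional test asks whether the genes of a list move, on balance, one way and does not compare the list with other genes. With an estimated correlation, no call of any comparison held. The lists covered PI3K-AKT-mTOR components, FoxO targets, sterol and fatty acid synthesis, glycolysis, ATF4 and amino acid synthesis, p53 targets, senescence, cell division, androgen receptor targets, the unfolded protein response, type I interferon, MHC class II, immediate early genes, ribosomal proteins and oxidative phosphorylation. Cell and tissue lists covered luminal, proximal luminal and basal epithelium, prostate lobe, seminal vesicle and epididymal genes, urothelium, smooth and skeletal muscle, fibroblast, endothelium, adipocyte, nerve, neuroendocrine, macrophage, neutrophil, T cell, B cell, mast cell and erythrocyte markers.

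The genes named in the report followed a rule. Pten, Phlpp1 and Phlpp2 were to be given always. For genotype, the rule took the 12 highest and 12 lowest log2 fold changes among genes past the threshold whose double mutant arrays both lay beyond both batch 1 wild type arrays. For age it took up to 6 each way among genes past the threshold, for the interaction up to 4 each way, and where too few passed, the 3 or 2 genes of smallest p, given as not passing. For batch it took 3 each way, and for each list up to 4 members of smallest p. Groups, models, lists, this rule and the alternatives were fixed before the data were examined, except for 1 alternative, the comparison with the batch 2 wild type arrays alone.

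The alternatives were quantile normalization, median centring of each array, filters on genes of low mean level (25th and 50th percentile), the mean of all probe sets of a gene, a trended robust variance, all probe sets whether named or not, array weights, leaving out each array in turn, no batch term, a replicate block in place of batch, batch as a random block (duplicateCorrelation), single batches, no age term, a fold threshold of 2, all 8 arrays in the age fit, an estimated correlation, and fry. Replicate numbers are shared between the wild type ages, so it was checked whether they pair arrays. Across genes, with each group's mean removed, arrays of the same number correlated at r = 0.553, 0.171 and 0.603 for replicates 1, 2 and 3, all above the 0.1 taken as a sign of pairing, although replicate 2 at 4 months matched replicate 3 at 6 months better (r = 0.464). Replicate 1 of both ages is also batch 1. Where it is displaced, removing the group mean moves replicates 2 and 3 of both ages to the same side. Positive correlations could therefore arise from batch alone, so this check cannot show pairing.

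The pipeline was tested on simulated data with the same arrays and groups, with 50 genes changed at each of 4 sizes. For genotype it recovered 28%, 46%, 74% and 98% of genes changed by 0.5, 1, 2 and 4 log2 units, with 14 false calls. For age it recovered 28%, 64%, 86% and 90%, with 10 false calls. Each gene had the same spread on all simulated arrays, while the batch 1 wild type arrays here stood apart. These shares and false calls may therefore not hold for the real arrays.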

Results

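Gene expression was measured on Affymetrix arrays in total RNA from mouse prostate, in animals of 129 Sv/C57BL6 background. The series title and design text name the question: what loss of Phlpp1, a phosphatase that removes an activating phosphate from the kinase AKT, does in a prostate that also lacks a copy of Pten, the lipid phosphatase that opposes PI3K. The samples were 6 wild type arrays, 3 at 4 months and 3 at 6 months of age, and 2 double mutant arrays (Pten+/-; Phlpp1-/-), 1 at each age. No single mutant is among the samples, so the parts of the 2 alleles cannot be told apart. Values were taken as log2 intensities, with array medians between 8.03 and 8.23. The number of arrays limits the precision of every value below. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

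Array names in the labels put 4 arrays in a first batch, holding both double mutants and replicate 1 of each wild type age, and the other 4 arrays, all wild type, in a second batch. The wild type arrays of batch 1 stood apart from the rest. On the first principal component, which held 47.9% of the variance over genes, the batch 1 wild type arrays were at -62.8 (4 months) and -27.3 (6 months), while the other 6 arrays lay between 4.09 and 27.8. The 4-month wild type replicate 1 had the lowest mean correlation with the other arrays across genes (Pearson r = 0.917, against 0.948 to 0.965 for the others), and its interquartile range was 2.11 against 2.29 to 2.44. Genes are not independent replicates, so these correlations rank arrays only. No pair of arrays held identical values, and the closest pair reached r = 0.986.

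**Figure D1:**
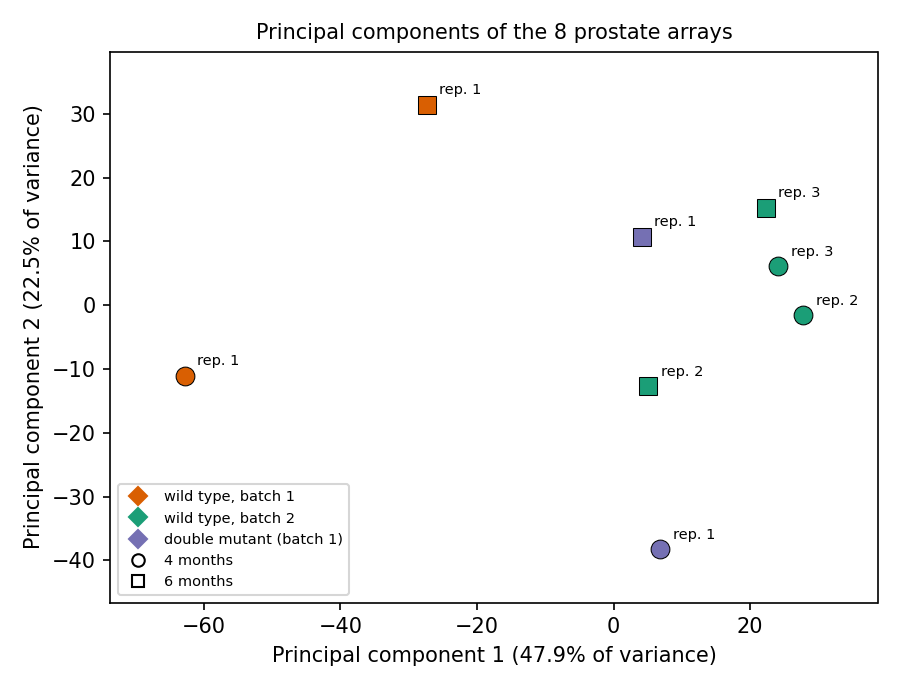
First principal component (horizontal axis, 47.9% of variance) against the second (vertical axis, 22.5%) over all genes, 1 point per array, with colour for wild type batch 1, wild type batch 2 and double mutant, circles for 4 months and squares for 6 months. The batch 1 wild type arrays lie at -62.8 and -27.3 on the first component, left of all other arrays.

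Phlpp1, the targeted phosphatase gene, was lower on the double mutant arrays than on 5 of the 6 wild type arrays. Its log2 level was 8.88 on the 4-month and 8.05 on the 6-month double mutant, against 10.37 ± 0.37 (SD, n = 3) in wild type at 4 months and 9.53 ± 1.35 (SD, n = 3) at 6 months. The wide spread at 6 months came from the array labelled wild type 6 months replicate 3, where Phlpp1 was at 8.06, while the other 6-month wild type arrays were at 9.79 and 10.72. With that array kept in the group its label gives, the fitted difference was -1.41 ± 0.91 (SE) and did not pass (adjusted p = 0.379). The labels do not say which part of Phlpp1 was removed, so a probe set outside that part would check nothing. Phlpp2, the related phosphatase, differed by 0.18 ± 0.18 (SE; adjusted p = 0.596), with levels of 8.72 and 8.99 on the double mutants and 8.63 ± 0.19 (SD, n = 6) in wild type. Pten had no probe set assigned to it alone and was not analysed here.

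**Figure D2:**
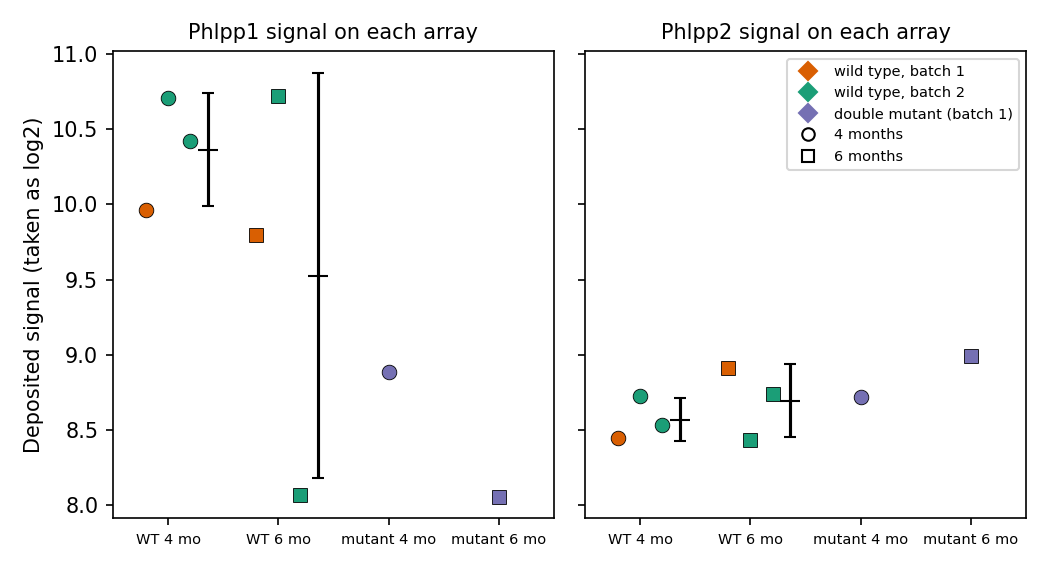
Log2 level of Phlpp1 and Phlpp2 (vertical axis) on each of the 8 arrays, 1 point per array, with a black bar for the mean ± SD of each wild type group (n = 3). Phlpp1 lies at 8.06 on the array labelled wild type 6 months replicate 3, beside 8.05 on the 6-month double mutant.

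In the double mutant prostate, set against wild type with age and batch in the model, Pgm3, Txndc12, Pde4b and Fmn1 were higher and Hdac7 was lower. Pgm3, an enzyme of the hexosamine pathway that feeds protein glycosylation, was 2.46-fold higher (log2 fold change 1.30 ± 0.11, SE; adjusted p = 0.0360), and Txndc12, a thioredoxin-like protein of the endoplasmic reticulum, 2.39-fold higher (1.25 ± 0.10; adjusted p = 0.0341). Pde4b, a phosphodiesterase that breaks down cyclic AMP, was higher by 1.23 ± 0.13, and Fmn1, a formin that builds actin filaments, by 1.28 ± 0.15. Hdac7, a class II histone deacetylase, was lower by 0.94 (SE 0.09; adjusted p = 0.0423). These sizes came mostly from the batch 1 wild type arrays. A comparison with the batch 2 wild type arrays alone, here and below, cannot tell genotype from batch, since both double mutants are of batch 1. Against the batch 2 wild type arrays alone the log2 fold changes were 0.36 for Pgm3, 0.20 for Txndc12, 0.45 for Pde4b, 0.33 for Fmn1 and -0.30 for Hdac7, none past the threshold (adjusted p from 0.1196 to 0.3504), and without the batch term they were 0.67, 0.55, 0.71, 0.64 and -0.51. For these 5 genes both double mutant arrays lay outside all 6 wild type arrays.

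With the batch term, other genes higher by at least 1 log2 unit included Rgs7, a regulator of G protein signalling (1.67 ± 0.16), Stxbp6, a syntaxin-binding protein (1.63 ± 0.15), Tfec, a transcription factor of the MiT family (1.60 ± 0.13), and Cntnap2, an adhesion protein of the neurexin family (1.46 ± 0.08). Gsdma3, a gasdermin, was higher by 1.41 ± 0.15, Abca5, an ABC transporter, by 1.36 ± 0.15, Gxylt2, a xylosyltransferase, by 1.29 ± 0.10, and the uncharacterised 2700046A07Rik by 1.47 ± 0.17. Among the genes that were lower, Sost, which encodes the Wnt inhibitor sclerostin, differed most (-1.65 ± 0.11), followed by Acacb, the acetyl-CoA carboxylase of mitochondria that restrains fatty acid oxidation (-1.30 ± 0.07). Also lower were Rhobtb1, an atypical Rho protein (-1.27 ± 0.08), Mtss2 (-1.15 ± 0.13), Arhgef2, a Rho exchange factor (-1.11 ± 0.12), and Trip6, a LIM protein of focal adhesions (-0.98 ± 0.11). So were the adhesion genes Pcdh7 (-1.07 ± 0.08) and L1cam (-0.95 ± 0.09), the annexin Anxa9 (-1.18 ± 0.14), the bicarbonate transporter Slc4a8 (-1.13 ± 0.12) and Ggt7 (-0.91 ± 0.09). Against the batch 2 wild type arrays alone, 9 of these genes took the opposite sign: Rgs7 (-0.024), Tfec (-0.074), Cntnap2 (-0.21), Gxylt2 (-0.041), Acacb (0.31), Anxa9 (0.68), Pcdh7 (0.15), L1cam (0.25) and Ggt7 (0.24). A changed sign there may reflect batch, which that comparison cannot tell from genotype. Adjusted p-values of the 24 genes chosen by rule ran from 0.0296 to 0.0489.

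In all, 182 of 18460 genes passed in limma, 129 higher and 53 lower in double mutants, with 34 changed at least 2-fold and a median absolute log2 fold change of 0.72. With the batch term the contrast rests on the batch 1 arrays, and on many of these genes the batch 2 wild type arrays lay near the double mutants. Rgs7 averaged 6.26 on the batch 1 wild type arrays, 7.93 on the double mutants and 7.95 on the batch 2 wild type arrays, and Acacb averaged 10.21, 8.91 and 8.60. For all 182 genes both double mutants lay beyond both batch 1 wild type arrays, since the calls rest on that contrast. They lay beyond all 6 wild type arrays for 64 of the 182 (52 higher, 12 lower). Over all genes this held for 9.73%, where chance gives 7.14%, but genes chosen in this way cannot be set against either share. Among the 182 genes, 144 also passed between batches in wild type, 143 of them with the batch 1 wild type arrays displaced in the same sense from both other sets. Of these, 102 were higher and 41 lower in double mutants, against 4.03 and 0.904 expected if the comparisons were independent. They are not, since both use the batch 1 wild type arrays: across genes the fold changes of both comparisons correlated at r = 0.850. In 20 simulations with no changed gene, sharing these arrays gave r = 0.578. All simulated arrays varied alike, unlike the batch 1 wild type arrays here, so 0.578 is no baseline for 0.850. The 0 shared genes of the simulations decide nothing, since with no changed gene hardly any call can arise. No gene passed in limma without the batch term (977 at an unadjusted p under 0.05) or against the batch 2 wild type arrays alone (3655), where 114 of the 182 kept their sign, and the 4 batch 1 arrays alone gave none (3172). Nor did any gene pass with a replicate block in place of batch (4069), and 2 passed with batch as a random block. The count rested on single arrays too: it was 0 without the wild type 4-month replicate 1, 2 or 3, the 6-month replicate 3 or the 6-month double mutant, 1 without the 4-month double mutant, 674 without the wild type 6-month replicate 2 and 3795 without the 6-month replicate 1, as leave-outs of genes changed, double mutant versus wild type. Median centring of the arrays shifted every genotype log2 fold change by 0.114, and the values above are on the deposited scale.

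**Figure D3:**
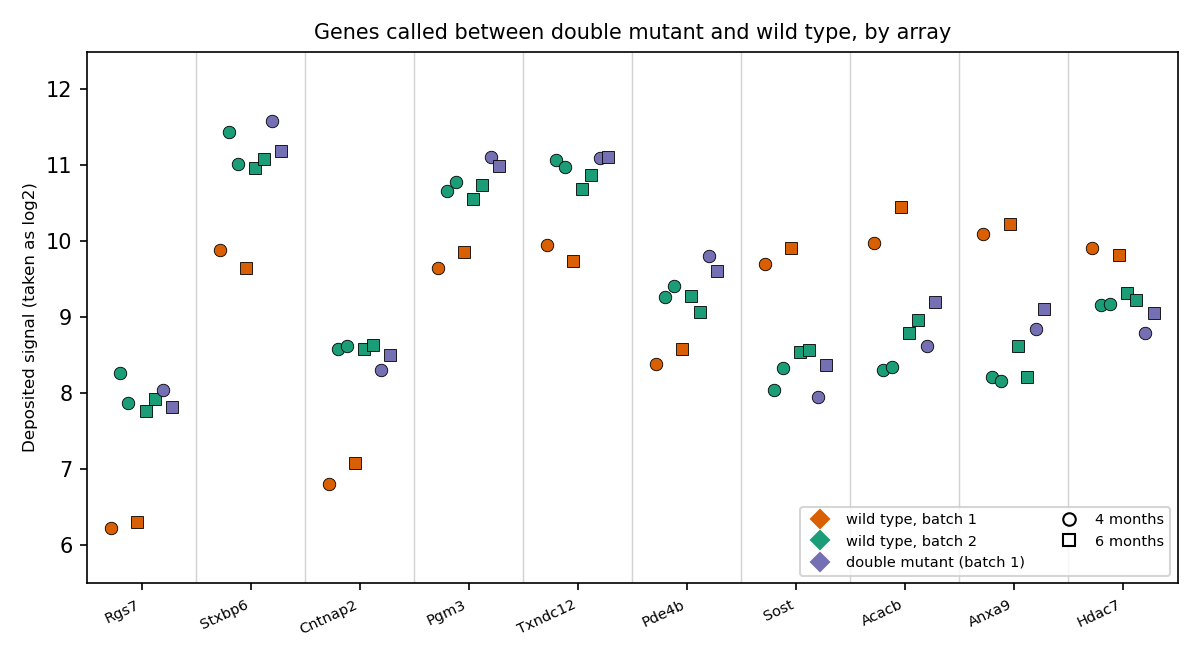
Log2 level (vertical axis) of Rgs7, Stxbp6, Cntnap2, Pgm3, Txndc12, Pde4b, Sost, Acacb, Anxa9 and Hdac7 on each of the 8 arrays, 1 point per array, coloured by wild type batch 1, wild type batch 2 and double mutant. For Rgs7 the batch 1 wild type arrays average 6.26 and the batch 2 wild type arrays 7.95, with the double mutants at 7.93.

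Among gene lists, stromal smooth muscle genes fell in the fit with batch (camera adjusted p = 0.000166, or 0.932 with an estimated correlation). All 12 measured members were lower in double mutants in that fit, with a median log2 fold change of -0.79. None passed over all genes and 11 passed when adjusted over the list alone. Smtn, which encodes smoothelin, was at -1.53 ± 0.34 (SE), Mylk, the myosin light chain kinase, at -0.83 ± 0.20, Synpo2 at -0.92 ± 0.25 and Acta2, smooth muscle actin, at -0.52 ± 0.16. The fibroblast and extracellular matrix list fell too, with 16 of 16 members lower and a median of -0.72 (adjusted p = 0.0194; adjusted p = 0.932 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The proteoglycan gene Bgn was at -1.05 ± 0.44 and the collagen gene Col6a1 at -1.06 ± 0.43. Both lists were lowest on the 4-month double mutant, and so were lists of other cell types: relative to the wild type mean, the medians on that array were -2.17 for adipocyte, -1.14 for endothelium, -0.71 for macrophage, -0.70 for mast cell and -0.64 for MHC class II genes. In the fit, 12 of 12 endothelium and 16 of 16 macrophage genes were lower, without a call for either list. Relative to the wild type mean, the median of the smooth muscle list was -0.77 on that array, -0.14 on the 6-month double mutant and 0.58 on the wild type 6-month replicate 1. The fibroblast list stood at -1.12, 0.098 and 0.56 on the same arrays. The 6-month double mutant thus lay within the wild type range, from -0.36 to 0.58 for smooth muscle and from -0.25 to 0.56 for fibroblast. In neither list did any gene have both double mutants beyond all 6 wild type arrays. Neither list passed without the wild type 6-month replicate 1 (smooth muscle 0.0951, fibroblast 0.427), and the fibroblast list did not pass without the 4-month double mutant (0.471).

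Genes of oxidative phosphorylation rose as a list, with 30 of 33 members higher and a median log2 fold change of 0.33 (adjusted p = 0.00018; adjusted p = 0.932 with an estimated correlation). Atp5c1, the gamma subunit of ATP synthase, passed over all genes (0.43 ± 0.05, SE; adjusted p = 0.0466), and 5 members passed when adjusted over the list alone, among them the succinate dehydrogenase genes Sdha (0.58 ± 0.09), Sdhc (0.72 ± 0.11) and Sdhd (0.67 ± 0.15). The unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, rose with 18 of 20 members higher and a median of 0.27 (adjusted p = 0.0123; adjusted p = 0.932 with an estimated correlation). Adjusted over the list alone 4 of its members passed, and none over all genes: the sensor Atf6 (0.67 ± 0.09), Dnajc3 (0.54 ± 0.11), Edem1 (0.48 ± 0.10) and the chaperone Canx (0.28 ± 0.06). The luminal epithelium list rose with 10 of 13 members higher and a median of 0.14 (adjusted p = 0.0296; adjusted p = 0.932 with an estimated correlation). It was the one list past the threshold with fry (adjusted p = 0.00322). None of its members passed over all genes and 6 passed when adjusted over the list alone, including the peptidase gene Dpp4 (1.29 ± 0.15), the luminal keratin Krt8 (0.26 ± 0.05), the homeobox gene Hoxb13 (0.43 ± 0.08) and the adhesion gene Epcam (0.65 ± 0.12). Sterol and fatty acid synthesis rose with 14 of 19 members higher and a median of 0.14 (adjusted p = 0.0410; adjusted p = 0.932 with an estimated correlation). None passed over all genes and 3 did adjusted over the list alone: Sqle, squalene epoxidase (0.80 ± 0.11), Cyp51 (0.81 ± 0.15) and Mvk, mevalonate kinase (0.46 ± 0.10). Against the batch 2 wild type arrays no list passed (smallest adjusted p = 0.104), and the oxidative phosphorylation and sterol lists pointed down (0.505 and 0.199). There Sdhc (-0.20), Canx (-0.14) and Cyp51 (-0.18) took the opposite sign and Sqle was at 0.012. The wild type 4-month replicate 1 gave the lowest list median of the 8 arrays for oxidative phosphorylation (-0.30), the unfolded protein response (-0.23) and sterol synthesis (-0.32).

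Of the 6 list calls, those for smooth muscle and fibroblast genes stood with quantile normalization, while oxidative phosphorylation (0.0808), the unfolded protein response (0.167), luminal epithelium (0.566) and sterol synthesis (0.437) did not pass there. Nor did luminal epithelium (0.0865) and sterol synthesis (0.178) with median centring, or oxidative phosphorylation (0.155) and sterol synthesis (0.954, pointing down) without a batch term. Among genes above the 25th percentile of mean level, the unfolded protein response (0.0701), luminal epithelium (0.175) and sterol synthesis (0.175) did not pass. Above the median of mean level, these (0.267, 0.499 and 0.509) and oxidative phosphorylation (0.0686) did not pass. Single arrays decided several calls. The unfolded protein response did not pass without the wild type 4-month replicate 1 (0.119) or the 6-month double mutant (0.142), nor luminal epithelium without the wild type 6-month replicate 1 (0.234) or 2 (0.0839). Sterol synthesis did not pass without the wild type 4-month replicate 1 (0.270), the 6-month replicate 2 (0.0817) or 3 (0.0566), or the 4-month double mutant (0.333), nor with the replicate block (0.114), batch as a random block (0.125) or the batch 1 arrays alone (0.106). Luminal epithelium did not pass with the batch 1 arrays alone either. Over 21 alternatives, the adjusted p of the 6 lists ranged from 4.08e-09 to 0.954.

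**Figure D4:**
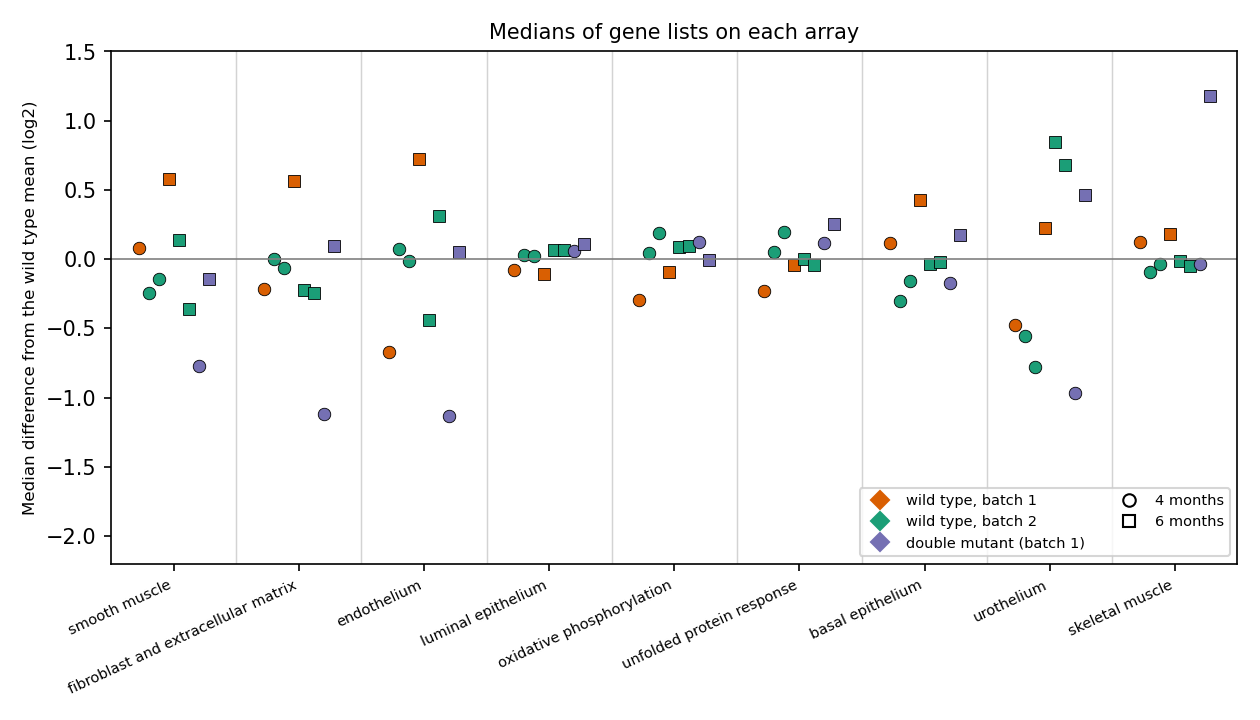
Median log2 level of each of 9 gene lists relative to the wild type mean (vertical axis), 1 point per array, coloured by wild type batch 1, wild type batch 2 and double mutant. The fibroblast list is at -1.12 on the 4-month double mutant and at 0.56 on the wild type 6-month replicate 1, and the skeletal muscle list is at 1.18 on the 6-month double mutant.

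The lists of the targeted pathway did not pass as wholes, though single members did. Pik3cb, a catalytic subunit of PI3K, was higher by 0.79 ± 0.07 (SE; adjusted p = 0.0410) with the batch term, by 0.32 without it and by 0.091 against the batch 2 wild type arrays, neither past the threshold, and was the 1 called among 20 PI3K-AKT-mTOR components, over all genes and adjusted over the list alone (list adjusted p = 0.628). Of 23 FoxO target genes, Sod2, mitochondrial superoxide dismutase, rose by 0.52 ± 0.06 (adjusted p = 0.0466) and 4 passed when adjusted over the list alone, with Sesn3 at 0.54 ± 0.08, Rbl2 at 0.53 ± 0.09 and Txnip at -0.43 ± 0.08 (list 0.998). In the basal epithelium list (0.0938), Trp63, the p63 transcription factor of basal cells, fell by 0.73 (SE 0.06; adjusted p = 0.0345), as did the integrin gene Itgb4 by 0.73 (SE 0.09; adjusted p = 0.0497), and 5 of 12 passed when adjusted over the list alone, among them Itga6 at 0.79 ± 0.12 and Col17a1 at -0.78 ± 0.13. Of 17 androgen receptor targets (0.805), 0 passed over all genes and 3 adjusted over the list alone, including Slc45a3 at 0.67 ± 0.11 and Azgp1 at 0.81 ± 0.16. No member of the remaining lists passed over all genes, and those with members past the threshold when adjusted over the list alone were the type I interferon response (0.305; Mx1 1.11 ± 0.17, Bst2 -0.45 ± 0.08 and Oas2 -0.42 ± 0.09), glycolysis (0.623; Ldha 0.56 ± 0.09 and Pfkl -0.49 ± 0.11), endothelium (0.131; Egfl7 -1.88 ± 0.29), mast cell (0.525; Kit -1.19 ± 0.17) and urothelium (0.857; Upk1b 0.49 ± 0.09). Against the batch 2 wild type arrays alone, Sod2 (-0.095), Itgb4 (0.15), Txnip (0.40), Pfkl (0.059) and Upk1b (-0.040) took the opposite sign.

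The other lists did not pass in either way, with these adjusted p-values. Lists of other cell types and tissues gave 0.180 for MHC class II presentation and for neuroendocrine genes, 0.305 for macrophage, 0.379 for seminal vesicle, nerve and glia, and proximal or progenitor-like luminal genes, 0.431 for neutrophil, and 0.525 for B cell and plasma cell and for skeletal muscle. Prostate lobe secretory genes gave 0.623, adipocyte genes 0.787, T cell genes 0.857, and epididymis and vas deferens genes 0.998. Lists of pathways gave 0.305 for immediate early genes, 0.339 for senescence and its secretory phenotype, 0.525 for p53 targets and for cytoplasmic ribosomal proteins, 0.527 for ATF4 and amino acid synthesis, and 0.805 for cell division. The test pointed up while the median was negative for glycolysis (-0.013), PI3K-AKT-mTOR components (-0.018), androgen receptor targets (-0.21), FoxO targets (-0.0083), urothelium (-0.075) and epididymis (-1.51e-05). The means of the androgen receptor, FoxO and urothelium lists were negative as well (-0.046, -0.012 and -0.045). For prostate lobe secretory genes the test pointed down while the mean was 0.31. The targeted genes, with 2 measured, and the erythrocyte list, with 3, were too small to test.

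Between 4 and 6 months, in wild type prostate alone, genes of the urothelium were higher at the later age. The cell and tissue lists were fixed as markers of what a dissected prostate could hold, neighbouring tissues included. Whether the 6-month samples held more of such tissue was not tested. The urothelium list rose with 6 of 6 members higher and a median log2 fold change of 1.19 (camera adjusted p = 7.95e-09; adjusted p = 0.329 with an estimated correlation), and 4 members passed when adjusted over the list alone, none over all genes. Upk2, a uroplakin of the bladder surface, averaged 8.2 ± 0.43 (SD, n = 3) at 4 and 10.20 ± 0.14 at 6 months, a difference of 2.01 ± 0.24 (SE). Krt20, a keratin of the urothelial surface, differed by 1.33 ± 0.20, Upk1a by 1.29 ± 0.23 and Upk3a by 1.10 ± 0.25. The list of proximal, progenitor-like luminal genes was called too, with 9 of 9 members higher at 6 months and a median of 0.49 (adjusted p = 9.3e-05; adjusted p = 0.870 with an estimated correlation), with none past the threshold singly: Krt7, a keratin of ductal epithelium, was at 1.79 ± 0.33, Ly6d at 2.44 ± 0.57, Wfdc2 at 1.24 ± 0.39 and Psca, prostate stem cell antigen, at 2.04 ± 1.10. The values of this list overlapped between ages. Relative to the wild type mean, its median was 1.00 on the 4-month replicate 1, the highest of the 8 arrays, and -1.04 and -0.70 on the 4-month replicates 2 and 3, against 0.43, 0.18 and 0.86 at 6 months.

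Of the age lists that follow, no member passed over all genes. Basal epithelium rose with 11 of 12 members higher and a median of 0.24 (adjusted p = 5.66e-06; adjusted p = 0.329 with an estimated correlation), and Trp63 passed adjusted over the list alone (0.40 ± 0.05, SE), with Krt5 at 0.43 ± 0.14. Cell division rose with 35 of 38 members higher and a median of 0.11 (1.38e-07), sterol and fatty acid synthesis with 17 of 19 and 0.13 (2.71e-06), and immediate early genes with 18 of 20 and 0.26 (1.48e-05). Within them the mitotic genes Nusap1 and Ccnb2 were at 0.24 ± 0.04 and 0.52 ± 0.17, Fasn, fatty acid synthase, at 0.38 ± 0.11, and the transcription factors Egr1 and Fosb at 1.30 ± 0.57 and 1.20 ± 0.62. Smooth muscle rose with 12 of 12 members higher and a median of 0.21 (0.00233), endothelium with 12 of 12 and 0.37 (0.0134), and oxidative phosphorylation with 25 of 33 and 0.058 (0.0205). These 6 lists each gave an adjusted p = 0.870 with an estimated correlation, and no member passed adjusted over the list alone. As medians relative to the wild type mean, every list of this paragraph but immediate early genes overlapped between ages. Smooth muscle was lowest among wild type arrays on the 6-month replicate 3 (-0.36). Endothelium was at -0.44 on the 6-month replicate 2, below 0.076 and -0.014 on the 4-month replicates 2 and 3. Basal epithelium was at 0.12 on the 4-month replicate 1, above -0.035 and -0.020 on the 6-month replicates 2 and 3. No list passed with fry (smallest adjusted p = 0.147). With camera among genes above the 25th percentile of mean level, oxidative phosphorylation did not pass (0.111). Above the median of mean level, neither oxidative phosphorylation (0.254) nor cell division (0.265) passed. Without either batch 1 array, which leaves the other alone in its batch, smooth muscle and endothelium (both 0.630), oxidative phosphorylation (0.789) and sterol synthesis (0.0601) did not pass, and endothelium and oxidative phosphorylation then pointed down. Nor did oxidative phosphorylation pass without the 4-month replicate 2 (0.248), smooth muscle without the 6-month replicate 2 (0.377), or endothelium (0.109) and the proximal luminal list (0.0634) without the 6-month replicate 3. Over the 17 alternatives run for most lists, the adjusted p of the 9 called lists ranged from 2.58e-15 to 0.890.

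No single gene passed between ages in limma (0 of 18460; 639 at an unadjusted p under 0.05; smallest adjusted p = 0.0750). The genes nearest to the threshold were Gsta4, a glutathione transferase (1.14 ± 0.03, SE; adjusted p = 0.0750), Sprr1a, a small proline-rich protein of squamous epithelium (3.89 ± 0.15; 0.171), and Nectin1, an adhesion gene (0.35 ± 0.02; 0.581). In the other direction they were Plet1 (-0.31 ± 0.03; 0.772), Sinhcaf (-0.37 ± 0.04; 0.887) and Lrrc42 (-0.24 ± 0.03; 0.887). All 6-month wild type arrays lay on one side of all 4-month wild type arrays for 579 genes, or 3.14%, where chance gives 10%, and no permutation of 3 against 3 arrays can go below a two-sided p of 0.1. The remaining 25 lists did not pass. They gave 0.0722 for the unfolded protein response, 0.125 for FoxO targets, 0.142 for B cell and for macrophage, 0.234 for adipocyte, 0.265 for p53 targets and 0.326 for glycolysis. Type I interferon, ATF4, epididymis and seminal vesicle genes gave 0.335, prostate lobe secretory genes 0.399, senescence 0.453, fibroblast 0.476, and neutrophil, MHC class II and ribosomal protein genes 0.547. PI3K-AKT-mTOR components, T cell, luminal epithelium and androgen receptor targets gave 0.718, mast cell 0.816, skeletal muscle 0.819, and neuroendocrine and nerve genes 0.971. Mean and test differed in sign for androgen receptor targets (mean -0.055, test up), skeletal muscle (0.018, down) and neuroendocrine genes (0.0059, down), and the nerve and glia list had a median of -0.024 with the test up.

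Whether age acted differently in the double mutants was asked with the interaction term, where each double mutant age has 1 array whose spread is assumed to equal that of wild type. Myh4, a fast myosin heavy chain of skeletal muscle, was at 10.75 on the 6-month double mutant and 6.97 on the 4-month double mutant, against 7.0 ± 0.12 and 7.03 ± 0.03 (SD, n = 3) in wild type of those ages, an interaction of 3.81 ± 0.09 (SE; adjusted p = 0.0686). Eno3, the muscle form of enolase, followed at 1.33 ± 0.05 (adjusted p = 0.0992). Perp, a p53 target in cell adhesion, was at -0.49 ± 0.04 and Gnb5, a G protein beta subunit, at -1.03 ± 0.09 (adjusted p = 0.969 for both). No gene passed in limma (0 of 18460; 613 at an unadjusted p under 0.05). Myh4 alone passed with quantile normalization (adjusted p = 0.0485), median centring (0.0336), a trended robust variance (0.0469) or no batch term (0.0443), and with batch as a random block both Myh4 and Atp2a1, the calcium pump of fast muscle, passed. Over its 14 alternatives, leaving out single arrays included, the adjusted p of Myh4 ran from 0.00786 to 1.00.

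Wild type arrays of both batches were compared because batch enters each model. Mrgpra6, a receptor gene, was higher in batch 2 by 2.25 ± 0.20 (SE; adjusted p = 0.0394), A130010J15Rik by 2.11 ± 0.18 and Cmpk1, a nucleotide kinase, by 1.98 ± 0.16. Rsph6a, a radial spoke gene of cilia, was lower in batch 2, with a log2 difference of -2.79 ± 0.32, as were Myl2, a myosin light chain (-2.43 ± 0.24), and Cyp4a12b, a cytochrome P450 gene (-2.21 ± 0.14). In total 891 genes passed in limma, 576 higher and 315 lower in batch 2, and 175 of them differed at least 2-fold. Leaving out the wild type 6-month replicate 1 gave 3882 genes, and leaving out any other wild type array gave 0, as counts of genes differing between array batches in wild type.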

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

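Among the tests in this part, those of a shift common to batch 1, of a narrower signal range, of genotype alone and of a genotype effect on skeletal muscle at both ages were chosen only after the result was seen.

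The wild type arrays of batch 1 differed from both other sets of arrays, and 182 genes passed for genotype with batch in the model. A shift common to all batch 1 arrays would put the double mutants, also of batch 1, near the batch 1 wild type arrays. Over the 891 genes called between batches they sat at a median of 0.236 of the way from batch 2 to batch 1 wild type (quartiles 0.0440 and 0.441; 0.0862 on the 4-month and 0.370 on the 6-month double mutant). These genes were chosen on the same difference that forms the divisor, which pulls the position below 1 by an amount not measured. The position therefore cannot decide on such a shift. On the first principal component the double mutants lay at 6.83 and 4.09, apart from the batch 1 wild type arrays (-62.8 and -27.3). That component was computed on these same arrays and is set largely by the batch 1 wild type arrays, so it cannot decide either. How far such a shift contributes stays open: for 174 of the 891 the double mutants sat past 0.5 of the way, among them Rsph6a (0.8202), Myl2 (0.6998) and Cyp4a12b (0.5992). A narrower signal range is argued against as the whole cause, since 1787 genes passed between batches once quantile normalization had given all arrays the same range. A count of calls depends on the residual spread and does not measure the size of the difference, so a part played by signal range stays open. The genotype of the double mutants alone is argued against as the whole cause too: the 891 genes were called among wild type arrays alone, and although leaving out any wild type array but the 6-month replicate 1 gave 0 calls, at least 4038 genes still had an unadjusted p under 0.05, where chance gives 923. The difference among wild type arrays is part of the pattern itself, so it is no separate test, though no double mutant array enters it. The condition of the individual batch 1 wild type samples stays open, untested, and so does a genotype effect in a part of the genes.

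Phlpp1 lay at 8.06 on the array labelled wild type 6 months replicate 3, far from the other wild type arrays, the next of which was at 9.79. Noise of this probe set cannot be told apart from a real change. The SD of Phlpp1 over the 8 arrays, 1.11, lay at percentile 99.1 of 3379 probe sets of like level, but the bound set beforehand, that so high an SD would exclude noise, was wrong: a noisy probe set has a high SD too, and the 8 arrays hold this array and the double mutants. Over the 5 other wild type arrays the SD was 0.426, at percentile 71.3 of the same probe sets. That spread is neither low nor extreme, so it does not decide either. For a wrong genotype label, 584 genes placed this array with both double mutants and apart from the other wild type arrays, or 3.16%, where chance gives 3.57%, rank 5 of the 6 wild type arrays, with 1651 for the wild type 4-month replicate 1. The bound set beforehand, that a lower rank would exclude a wrong label, was wrong, because the double mutants share little beyond chance (9.73% of genes outside all 6 wild type arrays, chance 7.14%) and the batch 1 wild type arrays share their batch. A wrong label therefore cannot be told apart from a change in this sample alone, and no biological explanation was tested.

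Skeletal muscle genes were high on the 6-month double mutant array, where 10 of the 14 listed genes were higher than on every other array. Acta1, Tnnc2 and Myh2 were not among them, at -0.082, -0.132 and -0.0014 from the wild type mean. Ckm, at 0.858, was not either. The genotype by age interaction rests on 1 double mutant array per age and assumes that these vary as wild type arrays do. It had a median of 1.38 over the 14 genes, all 14 positive. For Acta1 and Tnnc2 the positive sign came from the 4-month double mutant, at -0.958 and -1.05 from the wild type mean. On the 4-month double mutant 1 of 14 (7.14%) exceeded all 4-month wild type arrays, and the list median was -0.037 from the wild type mean. This is 1 array, its genes are not independent replicates, and the bar includes the outlying wild type 4-month replicate 1. A genotype effect at both ages therefore could not be decided. Skeletal muscle in the dissected 6-month double mutant sample could not be decided either. Of a second list, 47.8% (11 of 23) were highest on that array, against 6.18% of all genes. But Acta1, a skeletal actin already at 11.72 in wild type, differed there by -0.082 from the wild type mean, and urethral muscle lies next to the prostate. The design has 1 array for this genotype and age, so an effect of genotype limited to 6 months also stays open.

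Wild type values far from the other wild type arrays occurred for 3 lists as well, each as a list median relative to the wild type mean. The fibroblast and extracellular matrix list stood at 0.563 on the 6-month replicate 1, the B cell list at -0.120 on the 6-month replicate 2, and the epididymis and vas deferens list at 0.0325 on the 4-month replicate 1. Chance flags about 1 in 20 groups: 37 results were tested over the 6 wild type arrays, 4 stood out and 1.85 would by chance.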

How the results depend on the processing

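The comparison with the batch 2 wild type arrays was chosen after seeing the data. The cause of the differences given here was not tested.

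The count of genes changed, double mutant versus wild type (182), stayed within 1.5 times with the mean of all probe sets (181). It rose with quantile normalization (571), median centring (1949), genes above the 25th percentile (627) or the median (1306) of mean level, and no age term (400). Of the 182, 153, 169 and 114 passed again with quantile normalization, centring and no age term. It fell with all probe sets (80) and, by construction, a 2-fold threshold (34). It was 0 with a trended robust variance, array weights, no batch term (977 at an unadjusted p under 0.05), a replicate block (4069), batch 1 alone (3172) and the batch 2 wild type arrays (3655), and 2 with batch as a random block (Foxp4 and Zfp865, named after their values were seen). Leaving out each array gave 0 to 3795. Fewer arrays leave fewer degrees of freedom.

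Of the genes changed, 6 versus 4 months in wild type (0), 1 passed with median centring, with the 25th percentile filter and with no batch term, each time Sprr1a, 7 passed with the median filter and 15 with array weights, whose fit stopped before convergence. The count was 0 with the replicate block (604 at an unadjusted p under 0.05) and in the 6 leave-outs. Of the genes with a genotype by age interaction (0), 1 passed with quantile normalization, centring, trended robust variance and no batch term, and 2 with batch as a random block. The replicate block gave 0 (704 at an unadjusted p under 0.05). Leaving out either double mutant could give no interaction.

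The count of genes differing between array batches in wild type (891) was 1787 with quantile normalization, 3260 with centring, 2765 and 2629 with the filters, 0 with trended robust variance, and 0 to 3882 without each array. The gene lists shifted, double mutant versus wild type (6), numbered 2, 11 and 3 with quantile normalization, centring and the 25th percentile filter, 10 without a batch term (where calls were lost too: luminal epithelium 0.0865 and sterol synthesis 0.178 with centring, oxidative phosphorylation 0.155 without a batch term), 0 with an estimated correlation, 1 with fry, 0 against batch 2 wild type and 3 to 9 without each array. They numbered 6 with the replicate block and with batch as a random block, but not the same 6: sterol synthesis did not pass (0.114 and 0.125), while basal epithelium (0.0280) passed with the former and endothelium (0.0426) with the latter. The gene lists shifted, 6 versus 4 months in wild type (9), numbered 0 with an estimated correlation and with fry, 9 with the replicate block, and 7 to 13 otherwise.

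Signs of results past the threshold in either fit turned in these cases. Without a batch term, Anxa9, genotype, was at 0.056, and sterol and fatty acid synthesis gave 0.954 as an adjusted p. Against the batch 2 wild type arrays the log2 fold changes were Rgs7 -0.024, Tfec -0.074, Cntnap2 -0.21, Gxylt2 -0.041, Acacb 0.31, Anxa9 0.68, Pcdh7 0.15, L1cam 0.25, Ggt7 0.24, Sod2 -0.095 and Itgb4 0.15, and the adjusted p was 0.199 for sterol synthesis and 0.505 for oxidative phosphorylation. For age, without the batch 1 array of either age, oxidative phosphorylation gave 0.789, fibroblast 0.0126 and endothelium 0.630, where the leave-outs ranged from 2.78e-06 to 0.789 for the first and from 0.00014 to 0.630 for the last. Among named genes and lists under all alternatives, 6062 results kept sign and side of the threshold, 484 lost and 203 gained a call, and 21 past it in either fit turned. A further 276, below the threshold in both fits, took the other sign (161 for genes, 43 of them against batch 2 wild type, and 115 for lists). Of genes named for genotype in the report these included, against batch 2 wild type, Txnip (0.40), Cyp51 (-0.18), Canx (-0.14), Sdhc (-0.20), Pfkl (0.059) and Upk1b (-0.040), and without a batch term Txnip (0.12) and Canx (-0.0010). Signal over background limits weak genes: 1546 probe sets were nearly constant.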

Other observations

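List tests of the interaction were not in the fixed plan. The 4-month and 6-month double mutant arrays differed from each other in several gene groups. Immediate early genes, which respond to stress within minutes, were high on the 4-month double mutant, with a list median 0.73 above the wild type mean, and at 0.0064 on the 6-month double mutant. Egr1 was at 11.31 and 9.03 on these arrays, against 8.84 ± 0.10 (SD, n = 3) in 4-month and 10.14 ± 1.06 in 6-month wild type, and its interaction with age was -3.59 ± 1.15 (SE) without passing. The adipocyte list stood at -2.17 on the 4-month and 0.99 on the 6-month double mutant, but ranged from -1.91 to 1.59 over wild type arrays. Prostate lobe secretory genes stood at -0.13 and 0.53, with Sbp, a spermine-binding secretory protein, at 10.91 on the 6-month double mutant and at most 7.19 ± 0.45 (SD, n = 3) in a wild type age. In the interaction, 15 lists passed with camera, 11 up and 4 down, none with an estimated correlation (smallest adjusted p = 0.0615), and 1 with fry, skeletal muscle. The lists that pointed up included cell division (median 0.25), fibroblast (1.07), endothelium (0.81), MHC class II (0.48) and mast cell (0.55), and those that pointed down immediate early genes (-0.89), oxidative phosphorylation (-0.15) and ribosomal proteins (-0.23).

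The genes of urothelium that were higher at 6 months in wild type were also higher on the 6-month than on the 4-month double mutant. Upk2 was at 7.95 and 10.36 on these arrays, Krt20 at 6.95 and 8.13, Upk1a at 9.32 and 11.89, and Krt7 of the proximal luminal list at 8.54 and 10.47. With 1 array at each age this was not tested, nor was the share of neighbouring tissue in these samples. Among the 64 genotype calls beyond all 6 wild type arrays, Steap1, a gene of prostate epithelium chosen after its values were seen, differed by 1.16 ± 0.10 (SE) with the batch term, by 1.15 without it and by 1.15 against batch 2 wild type. Esr1, the estrogen receptor, Gfpt1, which opens the hexosamine pathway, and Golm1, a Golgi protein, were among these genes and were chosen after their values were seen (0.67, 0.71 and 1.14). Srf, a regulator of muscle and cytoskeletal genes, was lower, at -0.37, and was chosen in the same way.

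A hypothesis was that strain segments carried along with a targeted allele set neighbouring genes apart in the double mutants. Of the 100 measured genes nearest to Phlpp1, 16 had both double mutants beyond all 6 wild type arrays. Over 16465 windows of as many genes the median was 10, and 95.7% of windows had fewer than 16 and 97.7% had 16 or fewer. The windows overlap, so these shares rank the count only. These neighbours included Kdsr, Vps4b, Stk25 and Hdlbp, higher in double mutants and chosen after their values were seen. The count uses the order of arrays alone, so it also holds small differences. Without the batch term Serpinb3d was at -0.0012, and Serpinb12 and Slco6c1 were both at -0.080. None of the 16 passed in limma in that fit (smallest adjusted p = 0.622, Clasp1). Linked alleles of another strain may account for the excess of the 16 genes over the window median of 10, as a hypothesis, and not for all of them. Around Pten the count was 7, and 25.6% of windows had as few or fewer. The bound set beforehand, at or below the median of 10, would have excluded a segment there, but it left out the spread of windows, so a segment near Pten cannot be told apart from none. Sequence differences at probe sites and altered expression were not separated.

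For the comparison of ages, the 6 wild type arrays can be split in 10 ways, too few for a share under 0.05. The real split gave 0 genes, so all 10 splits give as many by construction and this count decides nothing. The highest other split gave 1 (1799 at an unadjusted p under 0.05, against 639 for the real one). The 3 other splits that part as many replicate pairs gave 574, 1172 and 1478 at an unadjusted p under 0.05 and no gene past the threshold.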
